A study of Mus musculus with 12 samples.

How the data were processed

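The 12 libraries came from follicular B cells of the mouse spleen, taken from 3 WT and 3 Jmjd1c KO animals. Each animal gave a library at 0 h and another at 2 h of anti-IgM, so there were 4 groups of 3 libraries. Per the labels' protocols, the cells were sorted and lysed in TRIzol, poly(A) RNA was selected with magnetic beads, and libraries were made with the NEBNext Ultra RNA kit. The labels also give each library a batch number from 1 to 3, which is shared between genotypes and times.

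Per the submitters' processing notes, reads were aligned with STAR to the mouse build mm10. The STAR version, the counting tool, its strand setting, its treatment of multi-mapping reads and the annotation are not given in the sources used here. The deposited values were raw counts per gene symbol, as whole numbers with different totals in each library, and each of the 12 files held 1 library. They had not been normalized, and the analysis started from these counts. Reads of a gene and an antisense or overlapping partner could therefore not be told apart. Counts of near-identical copies, such as ribosomal protein genes with processed pseudogenes, the Bcl2a1 family and the Hspa1a and Hspa1b pair, are uncertain for the same reason.

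The files listed the same 24046 symbols in the same order. Among these, 27 had names in the form of dates, as a spreadsheet writes them, and they were kept but are not named. A further 2 symbols stood on 2 lines each, which were kept apart. Gene positions came from a RefSeq gene table of GRCm38.p6, the assembly behind mm10, in which 94.4% of the tested symbols were found.

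Total counts ranged from 5666013 to 14153396 per library. A floor of 3 counts, the upper limit that a count of 0 allows, corresponded to between 0.183 and 1.02 CPM (counts scaled to a common library total), the highest value belonging to KO 2 h replicate 1. These floors cover counting error only, since reads without molecular identifiers are not independent molecules. The row for 45S ribosomal RNA, Rn45s, took between 0.418% and 52.3% of the counts of a library and was kept in the library sizes.

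Genes were kept with filterByExpr on the 4 groups, which left 12242. Library sizes were scaled with TMM factors (0.522 to 1.20). A quasi-likelihood negative binomial model with 1 mean per group was fitted to all 12 libraries in edgeR 4.0.16 under R 4.3.3. It gave 5 contrasts: KO against WT at 0 h and at 2 h, 2 h against 0 h in WT and in KO, and the difference between the responses of KO and WT. P values were adjusted with the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. All tests were two-sided. Fold changes are given as log2 values with a standard error (SE) derived from the F statistic, and expression as the mean ± SD of TMM-scaled CPM over 3 libraries. CPM is a value computed here from the deposited counts.

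Gene lists were tested with camera from limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the lists of 1 comparison. Camera asks whether a list's genes moved more than the other genes. It was run again with an estimated correlation, under which no list was called in any of the 5 comparisons. The fry test, which asks whether a list's genes move one way on balance, was run as well. Of 40 lists, covering programmes of B cells, markers of other cell types and signs of handling, 38 had at least 5 tested members. Immunoglobulin constant regions and mitochondrially encoded genes had fewer and were not tested. Counts within a list are given over all genes tested and adjusted over the list alone.

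The gene lists, the tests and the rule for naming genes were chosen before the data were examined. The rule named Jmjd1c in every comparison. For each comparison it also named the 8 called genes with the largest change in each direction, with a mean log2 CPM of at least 1 and no overlap between the libraries of the groups. Predicted genes, immunoglobulin variable segments and sex-linked genes were left out. Up to 4 members of each list with the smallest p were named too, and other members could be named where their list is described. Values of 3 such members are not reported here.

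The batch number paired the samples, because the labels say that it marks a shared batch and because both times of an animal carry it. Correlations of library deviations from the group means, across genes, were between -0.40 and 0.86 for libraries with the same number. For libraries with different numbers they were between -0.76 and 0.62. Of the 12 libraries, 4 correlated best with their own number in every other group. Fits with the batch or the animal as a block were run as alternatives. No pair of libraries within a group agreed within sampling noise: the chi-square per degree of freedom over genes was between 13.9 and 244, so none was treated as a duplicate.

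The other alternatives planned in advance were RLE size factors, no filter on low counts, a filter of 1 CPM in 6 libraries, a fit of only the groups compared, DESeq2 1.42.0, limma-voom with the animal as a random effect, and leaving out each library in turn. Added after the data were seen was a fit with the batch as a block and without KO 2 h replicate 1. Fits without both 2 h libraries of batch 1, without Rn45s, and with the log2 share of Rn45s as a covariate were added then too. So were DESeq2 with the batch as a block, and a KO against WT test on the counts of each animal summed over both times.

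The pipeline was tested on simulated counts in which 200 of the 12242 genes changed by known amounts. In the simulation of KO against WT at 0 h it recovered 8.96% of the genes changed 1.5-fold, 53.7% of those changed 2-fold and 84.8% of those changed 4-fold. For KO against WT at 2 h these shares were 11.9%, 52.2% and 80.3%, and for 2 h against 0 h in WT they were 11.9%, 46.3% and 81.8%.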

Results

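JMJD1C belongs to the JmjC family of histone demethylases, several of which act on methylated lysine 9 of histone H3. The series title places it in the control of autoimmunity and of the antibodies of heparin-induced thrombocytopenia, a clotting disorder driven by antibodies. Messenger RNA was sequenced from sorted follicular B cells, the main recirculating B cells of the spleen, of WT and Jmjd1c KO mice. Cells were taken at 0 h and after 2 h with anti-IgM, an antibody that cross-links the B cell receptor. There were 3 libraries in each of the 4 groups, from 6 animals that each gave both times. Total counts were 11539103, 8847418 and 12461136 for KO 0 h replicates 1 to 3, and 10991386, 8121347 and 13796131 for WT 0 h. They were 5666013, 8959165 and 14153396 for KO 2 h, and 8546014, 6501091 and 11274984 for WT 2 h.

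The libraries differed in the share of counts on Rn45s, the 45S ribosomal RNA precursor, which poly(A) selection should largely remove. At 2 h this share was 52.3% in KO replicate 1 and 24.8% in WT replicate 1, against 0.572% and 1.09% in the 0 h libraries of the same animals. It lay between 12.9% and 15.5% in the 4 libraries of batch 2 and was at most 0.624% in those of batch 3. Mki67, a marker of dividing cells, followed the same split. It was at 530 CPM in KO 2 h replicate 1, between 67.2 and 138 CPM in the other libraries with over 10% Rn45s, and between 8.81 and 14.5 CPM in the rest. The first principal component held 54.3% of the variance, with KO 2 h replicate 1 at 107 and every other library between -49.1 and 44.3. Y-linked genes and Xist placed the batch 1 animals of both genotypes as female and those of batches 2 and 3 as male, so sex was balanced between genotypes. As batch 1 was the only female batch, a difference confined to it cannot be told apart from one confined to females.

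**Figure D1:**
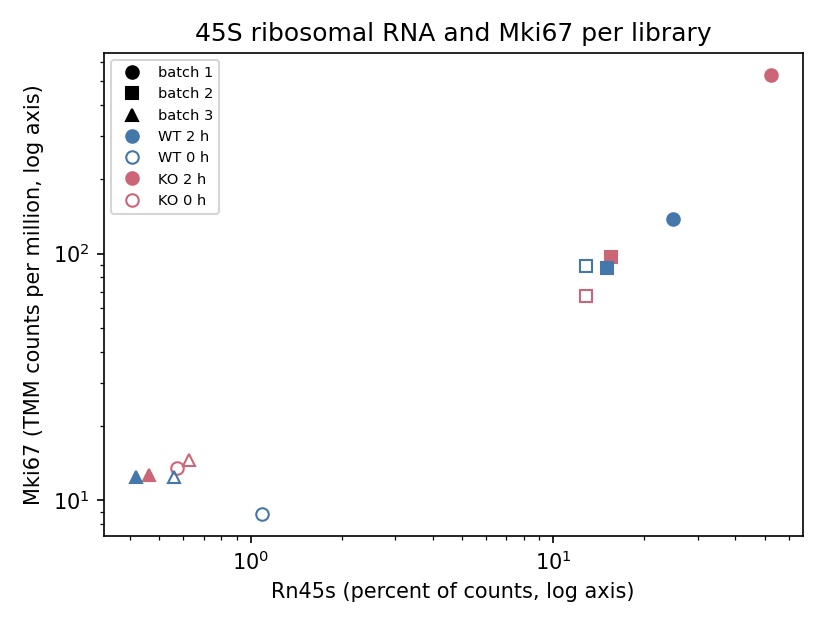
Share of counts on Rn45s (percent, log axis) against Mki67 (TMM-scaled CPM, log axis), with 1 point per library; shape marks the batch, colour the genotype and filling the time. KO 2 h replicate 1 sits apart at 52.3% and 530 CPM, and the libraries with the lowest Rn45s shares sit at the lowest Mki67 values.

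The targeted gene was measured first. Jmjd1c, on chromosome 10 from 67096351 to 67256326 (GRCm38), was lower in every KO library than in any WT library of the same time. At 0 h it was at 325 ± 35.7 CPM in WT and 221 ± 21.4 CPM in KO (SD, n = 3), a log2 difference of -0.56 ± 0.13 (SE). At 2 h it was at 296 ± 26.3 CPM in WT and 207 ± 7.30 CPM in KO, a log2 difference of -0.52 ± 0.13. Neither difference passed the test in edgeR (adjusted p = 0.9999 and adjusted p = 0.887). By chance 10% of genes would show no overlap between 3 and 3 libraries, counting both directions. DESeq2 with the batch as a block, added after the data were seen, called it at both times (adjusted p = 1.42e-09 and adjusted p = 4.25e-07). Over the other settings the lowest value was adjusted p = 0.0223 at 0 h, from the fit with the batch as a block and without both 2 h libraries of batch 1, and adjusted p = 0.174 at 2 h, from DESeq2 without a block. Which part of the gene was deleted is not given in the sources used here, so remaining counts may include exons outside it.

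**Figure D2:**
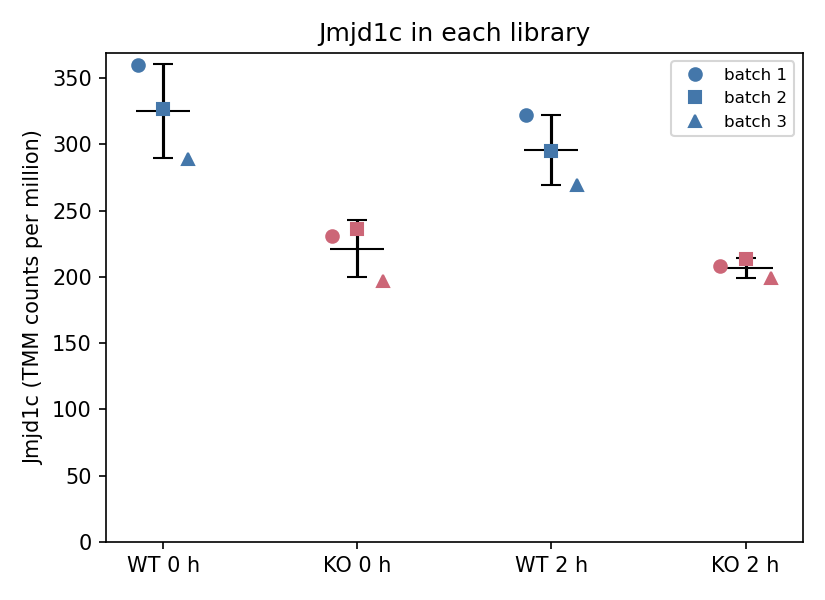
Jmjd1c in each library (TMM-scaled CPM, axis from 0) by genotype and time; shapes mark the batch, horizontal lines the mean and bars 1 SD (n = 3). KO libraries at 0 h average 221 CPM against 325 CPM in WT, and at 2 h 207 CPM against 296 CPM.

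WT cells were compared between 2 h of anti-IgM and 0 h. No library was kept for 2 h without anti-IgM, so changes from time in culture and handling cannot be told apart from those of receptor cross-linking, in either genotype. Among genes that met the naming rule S1pr3, a receptor for sphingosine 1-phosphate, rose the most, by 4.04 ± 0.36 on the log2 scale (SE). It went from 6.82 ± 1.67 to 111 ± 29.96 CPM. Myc, the transcription factor that drives growth, rose by 3.23 ± 0.35, from 99.6 ± 27.1 to 936 ± 293 CPM. Egr2, an immediate early transcription factor, rose by 3.05 ± 0.28, and Ahr, the aryl hydrocarbon receptor, by 3.01 ± 0.44. Cacna1i, a T-type calcium channel subunit, fell by 2.498 ± 0.30, from 204 ± 44.6 to 35.9 ± 10.7 CPM, and Icosl, the ligand of the T cell costimulator ICOS, fell by 2.22 ± 0.23, from 336 ± 11.6 to 71.9 ± 13.2 CPM. S1pr3 lies on chromosome 13 from 51408618 to 51422797, Myc on chromosome 15 from 61985341 to 61990361, Cacna1i on chromosome 15 from 80287238 to 80398292 and Icosl on chromosome 10 from 78069368 to 78079525.

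Among the other genes named by the rule, Hivep3, Mfsd2a, Lipg and Mreg rose by 3.79, 3.56, 3.47 and 3.44. Mfsd2a, a lysophospholipid transporter, and Lipg, endothelial lipase, were low, at 5.33 ± 2.93 and 3.92 ± 2.13 CPM at 2 h. Rag1, the recombinase of antigen receptor genes, fell by 2.52 from 3.42 CPM, and Cdkl1, Lifr and Qrfp fell by 2.42, 2.21 and 2.09, from 5.33, 2.62 and 7.34 CPM at 0 h. Emp3, an epithelial membrane protein, fell by 2.17 from 62.2 ± 11.2 CPM, and Pik3c2b, a class II phosphoinositide kinase, by 2.05 from 213 ± 24.9 CPM. Vegfa, the vascular growth factor, rose by 2.78, the chemokine Ccl4 by 2.86 and the interleukin 2 receptor chain Il2ra by 2.55. Cd83, an activation marker, rose by 1.72 and Gpr183, an oxysterol receptor that positions B cells, by 1.82.

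Genes of MYC activity and ribosome biogenesis rose together in WT. Of 36 tested members 34 rose and 0 fell, and adjusted over the list alone 36 rose (adjusted p = 1.38e-32, and adjusted p = 0.376 with an estimated correlation). Gnl3, a nucleolar GTPase, rose by 1.80, Nop16 by 1.79 and Nop58, a core protein of box C/D snoRNPs, by 1.40. Of 24 genes of lipid and cholesterol synthesis, 14 rose and 0 fell, and adjusted over the list alone 14 rose and 1 fell (adjusted p = 1.75e-08, and adjusted p = 0.417 with an estimated correlation). They included the sterol enzymes Sqle at 2.45 and Cyp51 at 2.02, and Insig1, a sterol sensor, at 2.11. Of 22 NF-kB targets, 12 rose and 2 fell, and adjusted over the list alone 14 rose and 2 fell (adjusted p = 1.38e-08, and adjusted p = 0.376 with an estimated correlation). Bcl2l1, which encodes the survival protein BCL-XL, rose by 2.36 and Bcl2a1b by 2.52, while Bcl3, an atypical IkB protein, fell by 1.505. Counts of Bcl2a1b and its copy Bcl2a1d, which rose by 2.40, are uncertain because their reads may be shared. Of 25 immediate early and activation genes, 9 rose and 0 fell, also adjusted over the list alone (adjusted p = 7.52e-08, and adjusted p = 0.469 with an estimated correlation). Egr3 rose by 2.58, Irf4, a regulator of plasma cell fate, by 2.40 and Bhlhe40 by 2.38.

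Of 15 heat shock and handling genes, 6 rose and 0 fell in WT, also adjusted over the list alone (adjusted p = 0.0106, and adjusted p = 0.647 with an estimated correlation). Hspd1, a mitochondrial chaperone that also stands in the MYC list, rose by 1.33, and Hsp90ab1 rose by 1.04. Of 18 genes of the unfolded protein response, 4 rose and 1 fell, and adjusted over the list alone 6 rose and 1 fell (adjusted p = 0.0385, and adjusted p = 0.658 with an estimated correlation). Hspa5, the chaperone BiP, rose by 0.86 and Ddit3, which encodes CHOP, by 1.01, while Eif2ak3, the sensor kinase PERK, fell by 1.04. This list was no longer called without WT 0 h replicate 3 (adjusted p = 0.112) or WT 2 h replicate 2 (adjusted p = 0.0857).

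The next 4 lists were called lower at 2 h in WT, with part of their members called. Of 22 regulators of G1 entry, 1 rose and 9 fell, also adjusted over the list alone (adjusted p = 0.00450, and adjusted p = 0.352 with an estimated correlation). Klf2, a quiescence and homing factor, fell by 1.69 and Cdkn1b, which encodes the inhibitor p27, by 1.11, while Cdk4 rose by 1.23. Of 13 genes of MHC class II presentation, 0 rose and 5 fell, also adjusted over the list alone (adjusted p = 1.22e-04, and adjusted p = 0.417 with an estimated correlation), among them Ifi30, a lysosomal thiol reductase, by 1.26 and H2-DMa, a peptide loading chaperone, by 1.08. Of 29 genes of B cell receptor signalling, 2 rose and 6 fell, and adjusted over the list alone 3 rose and 9 fell (adjusted p = 0.00841, and adjusted p = 0.701 with an estimated correlation). The receptor kinases Syk and Lyn fell by 1.45 and 0.77. Of 23 B cell identity genes, 3 rose and 7 fell, and adjusted over the list alone 4 rose and 9 fell (adjusted p = 0.0146, and adjusted p = 0.7503 with an estimated correlation). The lineage factors Tcf3 and Pax5 fell by 1.17 and 0.82.

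Of 38 interferon-stimulated genes, 0 rose and 5 fell in WT, also adjusted over the list alone (adjusted p = 0.00511, and adjusted p = 0.824 with an estimated correlation). Ddx58, which encodes the RNA sensor RIG-I, fell by 1.01 and the GTPase gene Gbp3 by 1.12. The list was not called without WT 0 h replicate 3 (adjusted p = 0.273). Of 19 histone lysine demethylases other than Jmjd1c, 2 rose and 5 fell, and adjusted over the list alone 2 rose and 8 fell (adjusted p = 0.0456, and adjusted p = 0.752 with an estimated correlation). Kdm2b rose by 1.99 and Kdm7a fell by 1.24. With the batch as a block the demethylase list was not called (adjusted p = 0.106), nor with the animal as a block (adjusted p = 0.103). It was also lost without WT 0 h replicate 1 (adjusted p = 0.0813), WT 2 h replicate 1 (adjusted p = 0.0728) or WT 2 h replicate 3 (adjusted p = 0.0813). With the batch as a block, genes of glycolysis and hypoxia (adjusted p = 0.0245, against adjusted p = 0.0834 without it) and marginal zone B cell markers (adjusted p = 0.0245, against adjusted p = 0.177) were also called higher. Jmjd1c itself differed by -0.14 ± 0.13 and was not called.

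In total 2419 genes were called in WT, 1310 higher and 1109 lower at 2 h, of which 557 and 328 changed over 2-fold. The count was 1529 without WT 0 h replicate 1, 1492 without WT 0 h replicate 3, 1349 without WT 2 h replicate 2 and 1551 without WT 2 h replicate 3. Without both 2 h libraries of batch 1 it was 3621, of which 2369 were among the 2419. The lists of receptor signalling (adjusted p = 0.0666), B cell identity (adjusted p = 0.157), interferon-stimulated genes (adjusted p = 0.0612) and demethylases (adjusted p = 0.0614) were then not called in WT.

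KO cells changed between 0 h and 2 h with much the same leading genes, among them S1pr3 at 3.79 ± 0.35 (SE), Hivep3 at 3.66, Mreg at 3.22, Ccl4 at 3.16, Ahr at 3.09, Myc at 3.07 ± 0.35 and Egr2 at 2.95. Il1r1, an interleukin 1 receptor, rose by 3.07, from 2.51 ± 1.58 to 20.6 ± 9.73 CPM. Cacna1i fell by 2.78, Icosl by 2.53, Cdkl1 by 2.51, Lifr by 2.41, Map3k9 by 2.35, the carboxypeptidase gene Cpm by 2.32, Pik3c2b by 2.28 and Rag1 by 2.23. In all 3316 genes were called, 1722 higher and 1594 lower at 2 h, of which 672 and 457 changed over 2-fold. Fitted on the 2 KO groups alone the count was 1626. Without both 2 h libraries of batch 1 it was 3922, of which 2992 were among the 3316.

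In KO 36 of 36 genes of MYC activity and ribosome biogenesis rose, also adjusted over the list alone (adjusted p = 1.67e-28, and adjusted p = 0.420 with an estimated correlation), with Nop16 at 1.97, Gnl3 at 1.82 and Nop58 at 1.64. Of 24 genes of lipid and cholesterol synthesis 14 rose and 0 fell, also adjusted over the list alone (adjusted p = 1.40e-05). Of 25 immediate early genes 9 rose and 0 fell, also adjusted over the list alone (adjusted p = 2.60e-06), with Egr3 at 2.23. Of 22 NF-kB targets 12 rose and 3 fell, and adjusted over the list alone 13 rose and 3 fell (adjusted p = 8.56e-06), with Bcl2l1 at 2.06. Of 15 heat shock genes 6 rose and 0 fell, also adjusted over the list alone (adjusted p = 0.00329), with Hspd1 at 1.39. With an estimated correlation each of these 4 lists had an adjusted p = 0.420.

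Of 29 genes of B cell receptor signalling, 1 rose and 15 fell in KO, and adjusted over the list alone 2 rose and 15 fell (adjusted p = 1.28e-04), among them Syk by 1.67 and Lyn by 1.01. Of 23 B cell identity genes 1 rose and 12 fell, and adjusted over the list alone 2 rose and 12 fell (adjusted p = 5.57e-04), with Tcf3 at -1.36 and Pax5 at -0.74. Of 13 MHC class II genes 0 rose and 5 fell, and adjusted over the list alone 6 fell (adjusted p = 8.48e-04), with Ifi30 at -1.23. Of 22 regulators of G1 entry 1 rose and 10 fell, and adjusted over the list alone 2 rose and 10 fell (adjusted p = 0.00232), with Klf2 at -1.59. Of 19 demethylases 2 rose and 7 fell, and adjusted over the list alone 2 rose and 11 fell (adjusted p = 0.00232), with Kdm7a at -1.70. With an estimated correlation each of these 5 lists had an adjusted p = 0.420. Of 17 alternative settings, the KO call of B cell identity held in 14 and that of demethylases in 13. Without both 2 h libraries of batch 1, 9 of the 14 lists called in KO were called in the same direction, and 8 with the batch as a block. Jmjd1c differed by -0.10 ± 0.13 between the times and was not called.

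A further 4 lists were called higher at 2 h in KO. Of 34 nuclear genes of the respiratory chain 11 rose and 0 fell, and adjusted over the list alone 11 rose and 1 fell (adjusted p = 8.48e-04, and adjusted p = 0.646 with an estimated correlation). Uqcrq, a complex III subunit, rose by 1.26, Cycs, which encodes cytochrome c, by 0.94 and Cox5a by 0.86. Of 39 cytosolic ribosomal protein genes 4 rose and 0 fell, and 0 adjusted over the list alone (adjusted p = 8.06e-04, and adjusted p = 0.767 with an estimated correlation), with Rpl10a at 0.61. Rps2 rose by 0.58. The change in Rps2, 2 h against 0 h in KO, was not called without KO 0 h replicate 2 (adjusted p = 0.0679) or from the KO groups alone (adjusted p = 0.103), nor from these alone was that in Rpl10a, 2 h against 0 h in KO (adjusted p = 0.0804). Of 26 genes of glycolysis and hypoxia 9 rose and 1 fell, also adjusted over the list alone (adjusted p = 0.0242, and adjusted p = 0.420 with an estimated correlation), with the hexokinase gene Hk2 at 2.31 and Ldha, lactate dehydrogenase, at 1.57. Of 29 proliferation genes 2 rose and 1 fell, and adjusted over the list alone 1 rose (adjusted p = 0.0176, and adjusted p = 0.767 with an estimated correlation), with Pcna, the DNA polymerase clamp, at 1.21.

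None of these 4 calls held without KO 2 h replicate 1, the library with 52.3% Rn45s and 530 CPM of Mki67. The values were then adjusted p = 0.0573 for the respiratory chain, adjusted p = 0.220 for ribosomal proteins, adjusted p = 0.140 for glycolysis and adjusted p = 0.726 for proliferation. The proliferation list was also lost without KO 0 h replicate 3 (adjusted p = 0.0543). With the batch as a block, germinal centre genes (adjusted p = 0.0425), the unfolded protein response (adjusted p = 0.0363) and marginal zone markers (adjusted p = 0.0448) were called higher too, against adjusted p = 0.0515, adjusted p = 0.0628 and adjusted p = 0.198 without it. With the animal as a block, interferon-stimulated genes were called lower (adjusted p = 0.0206, against adjusted p = 0.115).

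The 2 responses overlapped widely. Of the called genes 2180 were called in the same direction in both genotypes, 1200 higher and 980 lower, and 0 in opposite directions. Independent lists of these sizes would share 184 higher and 144 lower genes. All 2419 genes called in WT had the same sign in KO, 239 genes were called in WT and not in KO, and 1136 in KO and not in WT. Fitted on only the 2 groups of each response, the counts were 3295 in WT and 1626 in KO. Which genotype had more called genes therefore depended on the fit. Across genes the log2 responses correlated with Pearson's r of 0.859 and a slope of KO on WT of 1.12, and genes are not independent replicates. The responses share no libraries, but they share the batches.

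**Figure D3:**
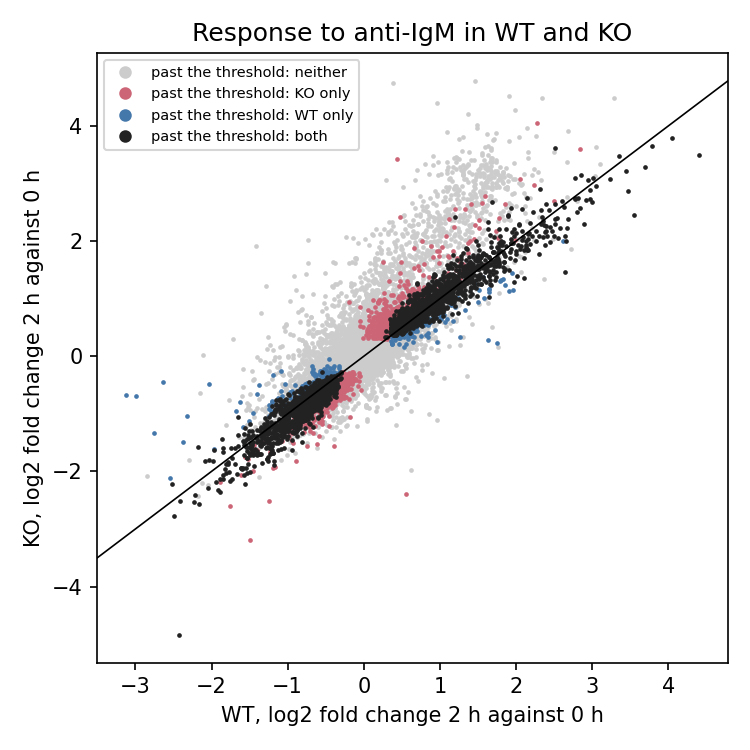
Log2 fold change at 2 h against 0 h in WT (horizontal) and KO (vertical), with 1 point per tested gene and the line of equal change. Black points passed the threshold in both genotypes, blue in WT and not KO, red in KO and not WT, and grey in neither; 2180 genes passed it in both in the same direction.

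KO and WT cells were compared at 0 h to ask what loss of Jmjd1c changed before stimulation. No gene was called in edgeR (0 of 12242, with 91 at an unadjusted p under 0.05 where chance gives 612), and limma-voom also called 0. The edgeR fit leaves the batch pairing out, although deviations of same-batch WT and KO libraries at 0 h correlated at 0.54 to 0.74. With fewer small p values than chance gives, its 0 calls do not show that nothing changed. DESeq2 called 1, Gad1, which encodes a glutamate decarboxylase and was chosen after its value was seen. It was at 32.9 ± 3.53 CPM in WT and 15.8 ± 2.88 CPM in KO, a log2 difference of -1.06 ± 0.22 (SE), with adjusted p = 0.9999 in edgeR and adjusted p = 0.0184 in DESeq2. Ptpn22, a phosphatase gene linked to autoimmunity, was at 52.7 ± 11.96 CPM in WT and 82.8 ± 5.62 CPM in KO (log2 0.65), and Sdc1, the plasma cell marker syndecan-1, was at 70.7 ± 9.45 and 47.8 ± 8.08 CPM (log2 -0.57). Neither was called. Blocking by batch, which pairs the samples, edgeR also called 0 genes (160 at an unadjusted p under 0.05). Among settings added after the data were seen, DESeq2 with that block called 4, all lower in KO: Jmjd1c (-0.55), Gad1 (-1.05), B3gnt7 (-0.94) and Pmepa1 (-0.74). In edgeR the block without both 2 h libraries of batch 1 called these 4 and Scd2 (-0.67). B3gnt7, Pmepa1 and Scd2 were chosen after their values were seen.

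The camera test called 7 lists at 0 h, although 0 members of any of them were called, also adjusted over the list alone. Heat shock and handling genes leaned higher in KO (median log2 0.18 over 15 members, 12 positive, adjusted p = 1.22e-04, and adjusted p = 0.626 with an estimated correlation), with Hspa1a at 1.06 and Dnaja1 at 0.27. Their medians were 0.19, -0.02 and 0.22 in batches 1, 2 and 3, and the call was lost without WT 0 h replicate 3 (adjusted p = 0.0900). Costimulation genes leaned higher (0.14 over 20 members, 18 positive, adjusted p = 0.00471), with Cd40 at 0.25. Their batch medians were 0.23, 0.14 and -0.01, and the call was lost without KO 0 h replicate 1 (adjusted p = 0.103). Interferon-stimulated genes leaned lower (-0.17 over 38 members, 9 positive, adjusted p = 0.00226), with the antiviral gene Mx2 at -1.35. Their batch medians were 0.20, -0.03 and -0.49. Without WT 0 h replicate 3 they leaned higher (adjusted p = 0.00244) and without KO 0 h replicate 2 they were not called (adjusted p = 0.276). T cell markers leaned lower (-0.36 over 17 members, 1 positive, adjusted p = 0.00353), with Bcl11b at -0.53. Their batch medians were 0.23, -1.08 and -0.07, and the call was lost without KO 0 h replicate 2 (adjusted p = 0.182) or WT 0 h replicate 2 (adjusted p = 0.845). With an estimated correlation the costimulation, interferon and T cell lists each had an adjusted p = 0.897.

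The remaining 0 h lists were called higher in KO with small medians. Marginal zone markers had a median of 0.07 over 15 members, 11 positive (adjusted p = 0.0211, and adjusted p = 0.413 with an estimated correlation), with S1pr3 at 0.51. They were lost without KO 0 h replicate 1 (adjusted p = 0.0570) or 2 (adjusted p = 0.180), or without WT 0 h replicate 1 (adjusted p = 0.164) or 3 (adjusted p = 0.0764). Germinal centre genes were split evenly, with a median of 0.03 over 16 members, 8 positive (adjusted p = 0.0231, and adjusted p = 0.897 with an estimated correlation). Bcl6, the master regulator of that state, was at 0.26 and Rgs13 at 0.72. Their batch medians were 0.30, -0.12 and 0.30, beside 1.23, -1.27 and 0.09 for neutrophil markers, which were not called. The germinal centre call was lost without KO 0 h replicate 2 (adjusted p = 0.653), WT 0 h replicate 1 (adjusted p = 0.496) or WT 0 h replicate 3 (adjusted p = 0.613). Autoimmunity-associated and atypical B cell genes had a median of 0.04 over 22 members, 12 positive (adjusted p = 0.0231, and adjusted p = 0.897 with an estimated correlation), with Fcrl5 at 0.88. They were lost without KO 0 h replicate 1 (adjusted p = 0.0768), KO 0 h replicate 2 (adjusted p = 0.157) or WT 0 h replicate 1 (adjusted p = 0.322), and with the Rn45s covariate and the batch block (adjusted p = 0.140). The number of lists called was 3 without KO 0 h replicate 2, 16 without KO 0 h replicate 3, 11 without WT 0 h replicate 1 and 14 without WT 0 h replicate 2. With the batch as a block, lipid and cholesterol synthesis (adjusted p = 0.00974, against adjusted p = 0.0596) and erythroid markers (adjusted p = 0.0237, against adjusted p = 0.113) were also called higher. The erythroid medians were 0.81, 0.70 and 0.32 in batches 1, 2 and 3. Erythroid transcripts were rare: Hbb-bs, a beta globin gene, averaged 5.12 ± 6.57 CPM in KO and 2.71 ± 3.47 CPM in WT at 0 h, and its log2 difference of 0.94 turned to -0.92 without KO 0 h replicate 2.

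At 2 h the comparison of KO with WT asked what differed between genotypes after 2 h with anti-IgM. The 39 cytosolic ribosomal protein genes tested were all at positive values in KO against WT, with a median log2 difference of 0.45, and 33 of the 34 nuclear genes of the respiratory chain were positive, with a median of 0.35. Rpl11 was at 342 ± 10.2 CPM in WT and 507 ± 184 CPM in KO (log2 0.57 ± 0.20), Rps19 at 263 ± 19.3 and 385 ± 118 CPM (0.55 ± 0.19), and Rps3 at 0.57. Ndufb7, a complex I subunit, was at 29.5 ± 1.10 and 48.2 ± 16.6 CPM (0.68 ± 0.19), and Cox5b, a complex IV subunit, at 0.45. No member of either list was called, also adjusted over the list alone. The camera test called both (adjusted p = 4.53e-25 and adjusted p = 5.58e-13), and with an estimated correlation each had an adjusted p = 0.779. Within batches 1, 2 and 3 the ribosomal protein median was 0.82, 0.09 and 0.29 and the respiratory chain median 0.77, 0.05 and 0.20, so most of each difference lay in the batch of KO 2 h replicate 1. In that batch markers of other cells went both ways in KO against WT, with medians of 2.02 for neutrophils (13 of 13 members), 1.85 for erythroid cells (9 of 9), 1.42 for megakaryocytes and platelets (5 of 6) and 0.44 for monocytes and macrophages (10 of 13), counting members higher in KO. They were -0.50 for T cells (6 of 17), -0.57 for NK cells (4 of 11) and -0.22 for dendritic cells (3 of 6). In batches 2 and 3 the medians were -1.14 and 0.35 for neutrophils, 0.999 and 0.41 for erythroid cells, and 0.18 and -0.066 for megakaryocytes and platelets.

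No single gene was called at 2 h in edgeR (0 of 12242, with 640 at an unadjusted p under 0.05 where chance gives 612), and limma-voom called 0. DESeq2 called 2, both lower in KO. Gad1 was at 39.2 ± 1.05 CPM in WT and 18.6 ± 6.75 CPM in KO (log2 -1.03 ± 0.23), and Rbl2, a pocket protein that restrains the cell cycle, at 74.1 ± 9.91 and 48.9 ± 4.75 CPM (log2 -0.59 ± 0.12). DESeq2 gave each an adjusted p = 0.0299 and edgeR an adjusted p = 0.887. Blocking by batch, edgeR called 0 genes (886 at an unadjusted p under 0.05). Among the added settings, DESeq2 with that block called 19, 4 higher and 15 lower in KO and Jmjd1c among them, and edgeR with the block and without both 2 h libraries of batch 1 called B3gnt7 (-1.10) and Scd2 (-0.90). Rbl2 was also called adjusted over the list alone, among 22 regulators of G1 entry. Of 22 plasma cell genes, 1 was higher and 1 lower adjusted over the list alone, the latter being Sdc1, at 67.2 ± 15.3 CPM in WT and 36.4 ± 7.93 CPM in KO (log2 -0.88 ± 0.21).

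Another 6 lists leaned one way at 2 h, with 0 called members, also adjusted over the list alone, and an adjusted p = 0.779 for each with an estimated correlation. Heat shock genes leaned higher in KO (median 0.21, 13 of 15 positive, adjusted p = 1.80e-04), with Hspe1 at 0.50, Hsp90aa1 at 0.40 and Hspa1a at 1.37, and batch medians of 0.35, 0.12 and 0.15. Demethylases leaned lower (median -0.19, 2 of 19 positive, adjusted p = 2.40e-04), with Kdm7a at -0.52 and Phf8 at -0.36, and batch medians of -0.59, -0.06 and -0.10. They were not called without both 2 h libraries of batch 1 (adjusted p = 0.0666), and their call held in 11 of 16 alternative settings. T cell markers leaned lower (median -0.38, 2 of 17 positive, adjusted p = 9.33e-04), with Cd3e at -0.90, and batch medians of -0.50, -0.78 and -0.07. That call was lost without KO 2 h replicate 2 (adjusted p = 0.110) or WT 2 h replicate 2 (adjusted p = 0.0708).

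Germinal centre genes leaned higher at 2 h (median 0.79, 15 of 16 positive, adjusted p = 2.40e-04), with Lmo2 at 0.79, Rgs13 at 0.73 and the death receptor gene Fas at 0.86. Proliferation genes leaned higher (median 0.78, 27 of 29 positive, adjusted p = 0.00202), with Pcna at 0.36, and genes of B cell receptor signalling leaned lower (median -0.16, 5 of 29 positive, adjusted p = 0.0119), with Dock8 at -0.22. The batch medians were 1.24, 0.09 and 0.20 for germinal centre genes, 1.44, -0.03 and 0.01 for proliferation genes, and -0.59, 0.01 and -0.08 for receptor signalling. Without KO 2 h replicate 1 the germinal centre and receptor lists were lost (adjusted p = 0.595 for both) and proliferation genes leaned lower (adjusted p = 0.0106). That fit had no block and kept WT 2 h replicate 1, at 24.8% Rn45s and 138 CPM of Mki67, without its batch partner. Without WT 2 h replicate 3 all 3 were lost (adjusted p = 0.0600, adjusted p = 0.289 and adjusted p = 0.473 for germinal centre, receptor and proliferation genes), and without KO 2 h replicate 2 the receptor list was lost (adjusted p = 0.0836). The number of lists called was 14 without KO 2 h replicate 3, 13 without WT 2 h replicate 2 and 5 without WT 2 h replicate 3. With the batch as a block erythroid markers were also called higher (median 1.39, adjusted p = 0.00861, against adjusted p = 0.0573), with Hbb-bs at 6.63 ± 6.29 CPM in KO and 2.45 ± 1.44 CPM in WT (log2 1.39 ± 1.66).

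**Figure D4:**
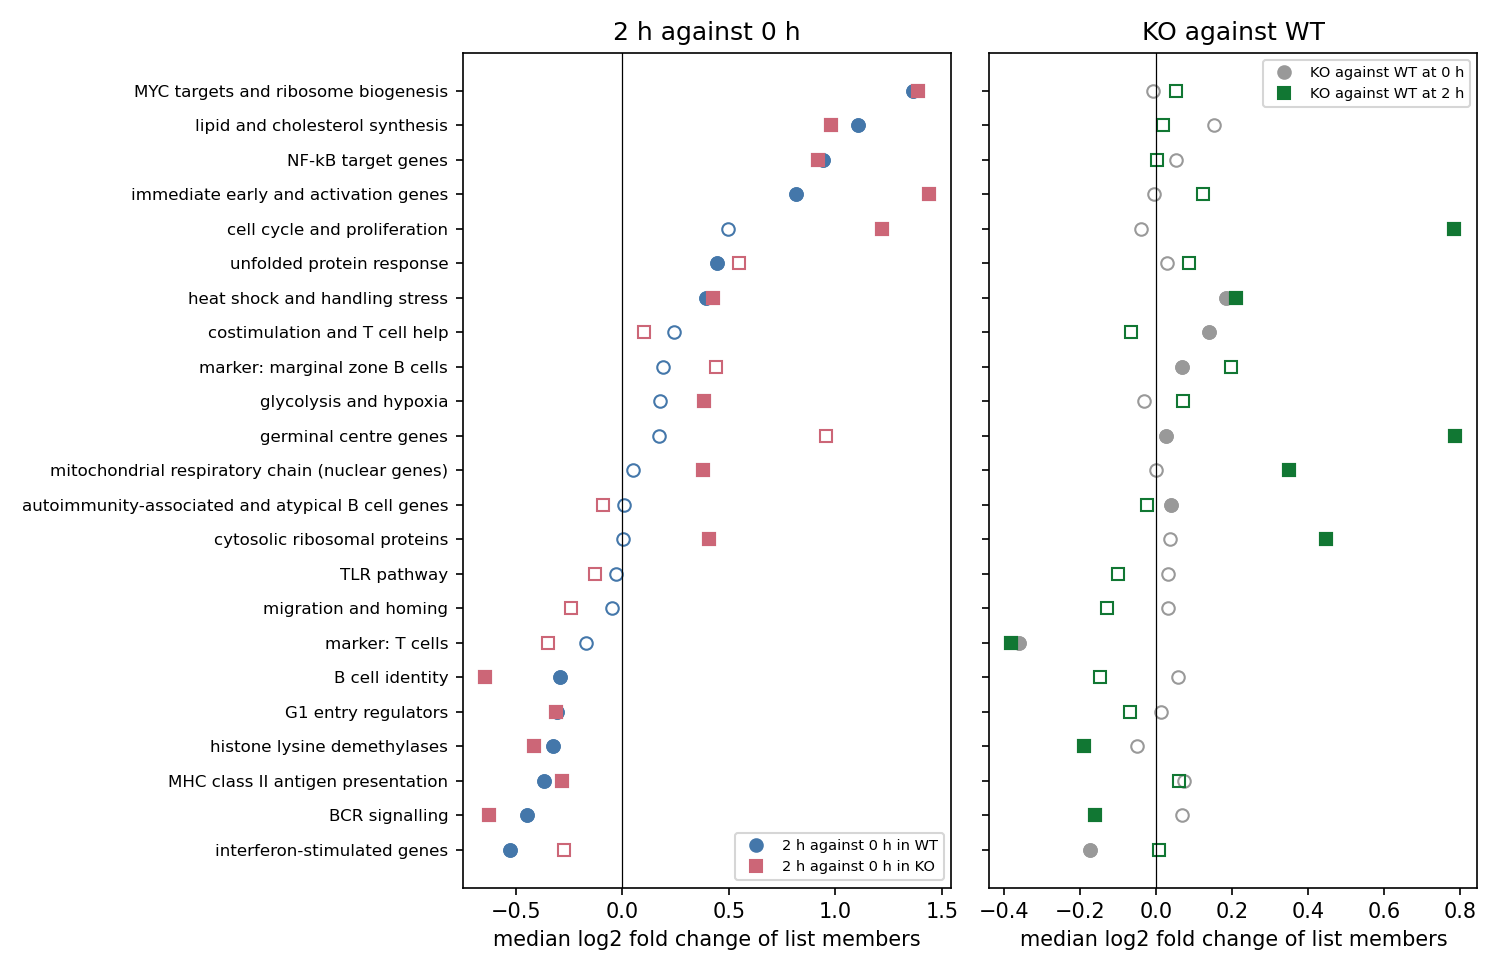
Median log2 fold change of the tested members of each list called in at least 1 comparison, for 2 h against 0 h (left) and KO against WT (right); filled points are lists called by camera with a preset correlation and open points are not. MYC targets lie furthest right among WT responses (median 1.36), and the cytosolic ribosomal proteins at 0.45 are called for KO against WT at 2 h.

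The difference between the responses of KO and WT was tested directly with the interaction contrast. The same ribosomal and mitochondrial lists led it. All 39 ribosomal protein genes had a larger change at 2 h in KO, with a median of 0.40 (adjusted p = 8.89e-21), as did 32 of 34 respiratory chain genes, with a median of 0.32 (adjusted p = 1.27e-13). Rpl11 differed by 0.53 ± 0.29, Rps19 by 0.50 ± 0.27, Ndufb7 by 0.65 ± 0.27 and Cox5b by 0.47 ± 0.21, and none was called. With an estimated correlation both lists had an adjusted p = 0.872. The differences lay mostly in batch 1: the ribosomal protein median of KO against WT went from 0.17 at 0 h to 0.82 at 2 h there, from -0.16 to 0.09 in batch 2 and from 0.08 to 0.29 in batch 3. For the respiratory chain it went from 0.06 to 0.77, from -0.12 to 0.05 and from 0.04 to 0.20.

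No gene was called in the interaction, with 0 of 12242 in edgeR and 0 in DESeq2 and limma-voom. In edgeR 40 had an unadjusted p under 0.05, fewer than the 612 that chance gives, so 0 calls do not show equal responses. Among the 3555 genes called in either response the smallest adjusted p was 0.993. Jmjd1c responded alike within error, with a difference of 0.04 ± 0.18. The camera test called 11 lists, 5 higher and 6 lower in KO, with 0 called members, also adjusted over the list alone. The number was 5 without KO 2 h replicate 1 and 6 without WT 2 h replicate 3.

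The markers of other cell types named next were called in no comparison without a block. For these the smallest adjusted p over the 5 comparisons was 0.120 for monocytes and macrophages, 0.0682 for neutrophils, 0.279 for NK cells, 0.509 for dendritic cells, 0.479 for megakaryocytes and platelets, 0.0573 for erythroid cells, 0.121 for B-1 cells and 0.112 for transitional B cells. It was 0.405 for cytokines and chemokines, 0.0524 for inhibitory receptors, 0.386 for plasma cell genes, 0.426 for STAT3 and cytokine feedback genes, 0.227 for apoptosis genes, 0.405 for H3K9 methyltransferases and readers, and 0.840 for sex-linked genes. Summed T cell markers were between 240 and 487 CPM per library.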

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

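Leaving out KO 2 h replicate 1 with the batch as a block was chosen after the results were seen. So was leaving out both 2 h libraries of batch 1, while leaving out each library in turn without a block was planned. The predictions for the length and ribosomal RNA tests were written down beforehand, but the Rn45s covariate fit was itself added after the data were seen. Of the 38 lists, 11 differed between the responses of KO and WT by the interaction contrast, with 0 called genes (40 at an unadjusted p under 0.05 in edgeR, 0 called in DESeq2 and limma-voom). The change at 2 h was higher in KO for cytosolic ribosomal proteins (median log2 0.40, adjusted p = 8.89e-21), the respiratory chain (0.32, adjusted p = 1.27e-13), proliferation (0.65, adjusted p = 0.00228), interferon-stimulated genes (0.36, adjusted p = 0.0376) and germinal centre genes (0.59, adjusted p = 0.0472). It was lower in KO for B cell receptor signalling (-0.19, adjusted p = 5.17e-04), B cell identity (-0.20, adjusted p = 0.00228) and costimulation (-0.27, adjusted p = 0.00257). It was also lower for demethylases (-0.15, adjusted p = 0.00431), the TLR pathway (-0.16, adjusted p = 0.0134) and migration and homing (-0.12, adjusted p = 0.0472). With an estimated correlation each of the 11 had an adjusted p = 0.872.

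Most of these calls rested on single libraries. Without KO 2 h replicate 1 the lists of costimulation and B cell identity (adjusted p = 0.371 for both), receptor signalling (adjusted p = 0.130), interferon-stimulated genes (adjusted p = 0.853), migration (adjusted p = 0.552) and demethylases (adjusted p = 0.326) were not called. The germinal centre (adjusted p = 0.371) and TLR lists (adjusted p = 0.961) changed direction without a call, and proliferation turned lower in KO (adjusted p = 0.00826). That fit had no block and kept WT 2 h replicate 1, at 24.8% Rn45s and 138 CPM of Mki67, without its batch partner. Proliferation medians of KO against WT were -0.20 and 0.02 in batches 2 and 3 at 0 h. At 2 h they were -0.03 and 0.01, so the turn cannot be read as an effect of genotype. Without WT 2 h replicate 3 the calls of B cell identity (adjusted p = 0.0770), germinal centre genes (adjusted p = 0.544), TLR pathway and migration (adjusted p = 0.0818 for both) and proliferation (adjusted p = 0.573) were lost. Germinal centre genes were also lost without KO 0 h replicate 1 (adjusted p = 0.110), KO 0 h replicate 3 (adjusted p = 0.263), WT 0 h replicate 2 (adjusted p = 0.955) or KO 2 h replicate 2 (adjusted p = 0.0622), and with the animal as a block (adjusted p = 0.0790). Interferon-stimulated genes were lost without KO 0 h replicate 2 (adjusted p = 0.332), WT 2 h replicate 1 (adjusted p = 0.234) or WT 2 h replicate 2 (adjusted p = 0.0584), with the batch as a block (adjusted p = 0.0682), and turned lower without WT 0 h replicate 3 (adjusted p = 0.0269).

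Migration genes were lost without KO 0 h replicate 2 (adjusted p = 0.210), WT 0 h replicate 1 (adjusted p = 0.162), WT 0 h replicate 3 (adjusted p = 0.0664), KO 2 h replicate 2 (adjusted p = 0.0622), WT 2 h replicate 1 (adjusted p = 0.0638) or WT 2 h replicate 2 (adjusted p = 0.0584). Proliferation was lost without KO 0 h replicate 3 (adjusted p = 0.0743) or WT 0 h replicate 2 (adjusted p = 0.395), the TLR pathway without WT 0 h replicate 2 (adjusted p = 0.0805), and demethylases without KO 0 h replicate 2 (adjusted p = 0.0655). The ribosomal protein and respiratory chain lists were called when any 1 library was left out, but the size of the difference lay mostly in batch 1. At 2 h the medians of KO against WT were 0.82, 0.09 and 0.29 for ribosomal proteins and 0.77, 0.05 and 0.20 for the respiratory chain in batches 1, 2 and 3.

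The ribosomal protein list at 2 h was weighed further. Without KO 2 h replicate 1 and with the batch as a block it was called higher in KO (adjusted p = 3.79e-14), which argues against that library as the whole cause. Over all genes the log2 difference and transcript length had a Spearman correlation of -0.173, so a length trend was present. Genes of matched transcript length had a median log2 difference of 0.119 of the list's own (0.0502 against 0.42), which argues against that trend as the whole cause. With the log2 share of Rn45s as a covariate and the batch as a block the list was called too (adjusted p = 2.40e-21). This test cannot decide on the amount of ribosomal RNA, because in batch 1 the share moved far more between times than between genotypes. It went from 0.572% at 0 h to 52.3% at 2 h in KO, and from 1.09% to 24.8% in WT. An effect of genotype stays open and its size is uncertain, with list medians of 0.82, 0.09 and 0.29 in batches 1, 2 and 3. The estimated correlation cannot decide on it, because no list was called under it in any comparison, even MYC targets in WT (median 1.36). RNA of other cells stays open too and was not tested for this list (neutrophil medians of 2.02, -1.14 and 0.35 in batches 1, 2 and 3).

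For the counts of genes, the 6 libraries of each comparison, or the 6 animals for the response difference, allow 10 splits, too few for a share under 0.05. Only 4 of the 10 part all pairs of the same batch number, the real one included, and among these the highest other count was 0 in each comparison. The real count was 0 for KO against WT at 0 h, at 2 h and for the response difference, where the highest other count was 0. There 10 of 10 splits gave as many, which a real count of 0 makes certain. The real count was 2419 for the response in WT and 3316 in KO, where the highest other count was 0 and 1 of 10 splits, the real one, gave as many. Each other split there put 0 h and 2 h libraries on both sides, which widens the spread within them, so their low counts add no support.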

How the results depend on the processing

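Of 2802 values of named genes under alternatives, 2783 had the same direction and side of the threshold, 3 were weaker, 9 stronger and 7 reversed. In edgeR, blocking by batch or animal changed the call of no named gene. The batch block gave 3048 genes for the WT response (2407 shared with the fit without it) and 3923 for KO (3265 shared). Blocking by animal, which pairs the 2 times of each animal, gave 2406 genes for WT (2124 shared) and 3260 for KO (2945 shared). Among planned settings, fitting only the groups compared gave 3295 genes for the WT response and 1626 for the KO response. DESeq2, also planned, called 1 gene at 0 h and 2 at 2 h between genotypes. With an estimated correlation 0 lists were called in each of the 5 comparisons. The fry test called 0 lists for KO against WT at 0 h, 0 at 2 h and 0 for the response difference, but 12 for WT and 20 for KO. Of these, camera also called 8 in WT and 12 in KO. In WT fry did not call receptor signalling (adjusted p = 0.0584), B cell identity (adjusted p = 0.0683), interferon-stimulated genes (adjusted p = 0.172) or demethylases (adjusted p = 0.0585). In KO it did not call ribosomal proteins (adjusted p = 0.111) or proliferation (adjusted p = 0.231). The cause was not tested.

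Leaving out 1 library at a time gave 1349 to 2245 genes for the WT response and 2281 to 3862 for KO, the highest without KO 2 h replicate 1. It gave 3 to 16 lists for KO against WT at 0 h, 5 to 14 at 2 h and 5 to 16 for the response difference. The response difference of Jmjd1c ran from -0.039 to 0.12, being negative without KO 0 h replicate 3 (-0.038), WT 0 h replicate 1 (-0.039) or WT 2 h replicate 3 (-0.022). Hbb-bs at 0 h ran from -0.92 without KO 0 h replicate 2 to 2.79 without WT 0 h replicate 2, at 0 to 12.6 CPM per library.

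The other settings were chosen after seeing the data. DESeq2 with the batch as a block called 4 genes at 0 h and 19 at 2 h, with Jmjd1c at -0.55 and -0.50. The Rn45s covariate with the batch as a block called 1 gene at 2 h and 4332 for the WT response. It ended the WT calls of receptor signalling (adjusted p = 0.209), B cell identity (adjusted p = 0.224) and demethylases (adjusted p = 0.555). In KO it ended those of the respiratory chain (adjusted p = 0.0791), ribosomal proteins (adjusted p = 0.0874), proliferation (adjusted p = 0.796) and demethylases (adjusted p = 0.0992). Leaving out KO 2 h replicate 1, with the batch as a block, called 1 gene at 0 h, 4745 for the WT response and 5 lists for the response difference. Leaving out both 2 h libraries of batch 1 gave 4 such lists, and with the batch as a block 3 lists, 5 genes at 0 h, 2 at 2 h, 5187 for the WT and 5492 for the KO response, with Jmjd1c at -0.56 at 0 h (adjusted p = 0.0223). Hbb-bs at 2 h was reversed in limma-voom (-1.95), in DESeq2 with the batch as a block (-0.095) and without KO 2 h replicate 1 with the batch as a block (-0.72). For the sums per animal, the test gave 0 genes without a block, 9 with a filter on the sums, and 78 with the batch as a block and without the 2 h libraries of batch 1. The cause was not tested.

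In the simulation of KO against WT at 0 h, 8.96% of 1.5-fold changes were recovered, and 23.9% with the batch as a block. The second run also used the spread estimated with that block. Neither run varied depth or sample number, and neither held a batch effect, so they do not show what limits the real fits. KO 2 h replicate 1 had 2700912 counts outside Rn45s.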

Other observations

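The tests on sums per animal, on the source of the proliferation transcripts and on Xist were chosen after the results were seen. Summing both times of each animal, with the batch as a block, called 8 genes between KO and WT. All had the same sign in 3 of 3 batches, which adds no support, because genes called with that block will mostly have it. Lower in KO were Armc9 (log2 -0.93, adjusted p = 0.00539), B3gnt7 (-1.04, adjusted p = 0.00629), Sdc1 (-0.64, adjusted p = 0.00808), Gad1 (-1.04, adjusted p = 0.0211) and Cables1 (-0.61, adjusted p = 0.0442). Higher were Lmo2 (0.54, adjusted p = 0.0211), Ccl4 (0.75, adjusted p = 0.0369) and Sema7a (0.61, adjusted p = 0.0369). Armc9, B3gnt7, Gad1, Cables1 and Sema7a were chosen after their values were seen, and Sdc1, Lmo2 and Ccl4 belong to fixed lists. Jmjd1c was at -0.54 (adjusted p = 0.0547), and was called without the 2 h libraries of batch 1 (-0.54, adjusted p = 0.00466), where 78 genes were. Without a block 0 genes were called, and of the 4 swaps of genotype within batches, the real one included, the highest other gave 2 genes. That many swaps are too few for a share under 0.05. All 8 genes were also called without the 2 h libraries of batch 1, a test on the remaining libraries and so not an independent one.

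In 6 libraries with Rn45s above 10% of counts, proliferation transcripts were high in both genotypes. Mki67 was between 67.2 and 530 CPM in these and between 8.81 and 14.5 CPM in the others. A candidate explanation is RNA of 1 outside source, such as dividing cells, added in different amounts. The excess of the 29 proliferation genes per excess of Rn45s then should be similar between libraries, and its highest value was 1.64 times the lowest, while the excess itself differed 7.97-fold. That range rests on KO 2 h replicate 1, with an excess of 1640 per 1e6 counts outside Rn45s, against 206 to 476.5 in the other 5 libraries. Both extremes of the ratio lie among those 5, so without KO 2 h replicate 1 the test tells little. Xist in the male batch 2 libraries, at 32.4 to 53.5 CPM, was at least 22.1 times the 0.864 to 1.47 CPM of the male batch 3 libraries. This argues against the sorted animals as the only source of RNA in batch 2. It does not show that the proliferation transcripts or Rn45s came with the Xist, and it does not cover the 2 h libraries of batch 1. In KO 2 h replicate 1, from a female, Y-linked genes summed to 48.1 CPM, against at most 11.9 CPM in the other female libraries. The source of such RNA may lie in handling, but the labels give nothing to test it.

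With the animal as a block, neutrophil markers were called higher in the response difference (adjusted p = 0.0477, against adjusted p = 0.0682 without it). They were not called with the batch as a block (adjusted p = 0.0885) or, without a block, with an estimated correlation (adjusted p = 0.872).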
